A study of Mus musculus with 12 samples.

How the data were processed

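Kidney RNA of 12 mice was profiled: WT and Smad3 KO, each as normal, UUO at day 5 and anti-GBM glomerulonephritis at day 10, with 2 libraries per group and groups of 8 mice in the UUO protocol. Per the labels' protocols, total RNA was depleted of ribosomal RNA, the longer RNA was taken from a urea gel, and libraries were made from it. Animals of both genders were used in the UUO protocol per the labels, and the sex of each is not given. Reads were aligned with Bowtie 0.12.7 to mm9, per the submitters' processing notes; how the transcripts were assembled or predicted and how reads were assigned to them is not recorded. No strand setting is recorded either, so reads of overlapping and antisense transcripts cannot be told apart.

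Each table gives, per the file headers, the number of uniquely mapped reads (counts) of each putative noncoding transcript, its length, and the best database match. The authors also gave RPKM; these values equal the reads per length and per total of the reads listed in the same table, with a largest relative deviation of 4.996e-15. The share of each transcript covered is a percent, per the file headers. The mean depth over the transcript is the deposited signal (coverage depth), and with the counts and lengths it gives a read length of 90 bases. Only transcripts with 1 or more reads are listed, so a transcript missing from a table was taken as 0. Lengths and matches were the same in all 12 tables for every transcript. The tables list no annotated protein-coding genes, though some transcripts match elements of mRNAs, such as untranslated regions. Per the file headers transcripts are named by running numbers; those with a match carry it in the text, and 160 of 182 matches to Ensembl transcripts got a gene name from the reference annotation of the same genome build. The tables pair no other number with a gene, and no test used the RFAM matches.

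Samples were grouped by the genotype and disease model of the labels; replicate numbers only tell animals of a group apart. The counts were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, the filter of filterByExpr by group (24816 of 42452 transcripts kept, 8035 matched and 16781 predicted), a model with 1 mean per group, robust quasi-likelihood fit, and F tests of 11 contrasts. Transcripts with a Benjamini-Hochberg adjusted p under 0.05 were called. All adjusted p-values come from this test unless DESeq2, limma, camera or fry is named. With 2 libraries against 2 a permutation cannot give a p below 0.3333, so calls rest on the spread pooled over the 12 libraries. Groups differed in spread: the chi-square per degree of freedom between the replicates' counts ran from 21.48 (WT normal) to 474.6 (KO anti-GBM). A pooled spread can make p-values too small for noisy groups and too large for others, so counts of calls are not equally calibrated across comparisons. CPM values are scaled by TMM and means are given with SD over 2 libraries; log2 fold changes are from edgeR, with the standard error from the F statistic. A group at 0 reads was set at a floor of 3 counts over the group. Floors and intervals cover counting error only, since reads are not independent molecules.

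These comparisons, the tests, the alternatives for each and the rule for named transcripts were chosen before the data were examined. The rule takes, per comparison, up to 8 higher and 8 lower matched transcripts, small RNA genes left out, of largest absolute log2 fold change among those called, with a mean of 10 CPM or more and, in comparisons of 2 groups, group values that do not overlap. Predicted transcripts have no gene name and were left out as the rule leaves out unnamed gene models; those in the text stand outside it. For the interactions and the averaged genotype, with 4 or 6 groups, overlap was not asked about, and there some groups do overlap. It gave 75 results. Of these the text names part, with other calls where a comparison had few, and elements of known RNAs chosen after the names were seen. The rule's fixed readouts, Smad3 among them, are protein-coding and were not analysed here. The fixed gene lists and cell type markers had at most 4 members in the tables against 5 needed, so lists were not tested. In their place 18 classes of database match, chosen after seeing the data, were tested with limma's camera (limma 3.58.1, inter-gene correlation 0.01, log2 CPM with prior count 2), with an estimated correlation, and with fry. Genes near Smad3 were not analysed, as the tables give no coordinates.

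Overlap of both WT models was set beside 20 simulations of unchanged groups that share controls, with the same spread of a transcript in all groups. Breadth of coverage was the median ratio of covered length to that of randomly placed reads, over transcripts longer than 500 bases with 20 to 200 reads. Libraries were thinned to 4595261 reads, the smallest total, to compare numbers of listed transcripts.

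Alternatives were DESeq2 size factors (DESeq2 1.42.0), library size alone, the DESeq2 Wald test, no filter on low counts, a filter of CPM 1 or more in 2 libraries, fits of only the groups compared, limma-trend on log2 of RPKM plus 1 or plus 0.1, a required absolute log2 fold change of 1, and each of the 12 libraries left out. Leaving out a library leaves a group of 1, whose library is taken to vary like the others. Chosen after seeing the data were fits of the 9 libraries of higher breadth (which leave 1 library each in WT UUO, KO UUO and KO anti-GBM), voom with quality weights, breadth or the Xist level as a covariate, and the holding of the 24816 transcripts in fits with fewer libraries. With the filter applied again to 11 libraries, 32560 to 35973 transcripts entered and the prior degrees of freedom of the spread became infinite, against 17.4 with 12 libraries.

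The method was tested on simulated counts of WT UUO against WT normal for 24816 transcripts. Of these 200 were changed, all picked among transcripts with a mean of 10 CPM or more. Each transcript had the same spread in all groups. The edgeR test recovered 24% of changes of log2 size 2, 54% of size 3, 94% of size 4 and 100% of size 6, and called 13 of 19891 unchanged transcripts; DESeq2 recovered 36%, 84%, 100% and 100% and called 45. Changes under a log2 size of 3 were therefore often missed at this number of libraries. Figures were drawn with matplotlib 3.10.9.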

Results

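The data are noncoding RNA profiles of mouse kidney (C57BL/6J) from wild-type (WT) and Smad3 knockout (KO) animals, where Smad3 is the transcription factor that carries the TGF-β signal to the nucleus. Kidneys were normal, obstructed for 5 days by ligation of the left ureter (unilateral ureteral obstruction, UUO), or taken at day 10 of a glomerulonephritis raised with sheep antibody to glomerular basement membrane (anti-GBM) at 60 μg/g body weight. Each of the 6 groups held 2 libraries, 12 in all. The tables list 42452 putative noncoding transcripts, of which 10852 have a match in sequence databases and 31600 are predicted transcripts without one. Reads on these transcripts came to between 4595261 (WT UUO 1) and 7342937 (WT UUO 2) per library. The series title asks for genes tied to TGF-β and Smad3 in renal inflammation and fibrosis; Smad3 itself, the collagens and the other protein-coding readouts of that question are not in these tables and were not analysed here.

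The matched transcript ncRNA_aligned_2133, 5262 bases long and matched to a human long noncoding RNA entry, stood apart by genotype. It had 0 reads in all 6 KO libraries and between 37 and 177 reads in each of the 6 WT libraries, a mean of 11.2 ± 7.94 CPM (SD, n = 6). Against a floor of 3 counts over the KO libraries, 0.0891 CPM, its WT level was at least 126-fold higher. The genotype difference averaged over the 3 states passed the edgeR test with adjusted p = 6.57e-05, and its lowest and highest adjusted p in the 12 fits without 1 library were 1.96e-05 and 0.00218. Of the 216 ways to assign the genotypes to the 12 libraries within states, the real one alone gave a transcript with 10 or more reads in each of the 6 libraries taken as WT and none in the 6 taken as KO. With 1 or more reads asked in place of 10 the real arrangement gave 16 transcripts, and another arrangement gave 53. The transcript was chosen after its values were seen, because its mean over all 12 libraries, KO included, lies below the 10 CPM asked of named transcripts.

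A few RNAs took much of each library. Transcript ncRNA_aligned_3554, 16248 bases long against 16299 for the mouse mitochondrial chromosome, held 35.73% of the reads of WT normal 2 and 35.16% of those of KO normal 1. In KO anti-GBM 1, KO UUO 1 and WT UUO 1 it held only 3.03%, 3.68% and 1.949%, and ncRNA_aligned_7824 held 36.35%, 15.68% and 16.53%. The best database match of this 290-base transcript is a mouse long noncoding RNA entry. It was named here after the model of RNase P RNA, the RNA of the enzyme that trims tRNA precursors, a name that this match does not give. In the other 9 libraries ncRNA_aligned_7824 held between 1.703% and 6.903%. The same 3 libraries covered their transcripts less broadly than their read numbers allow. Their ratio of covered length to that of randomly placed reads was 0.285 to 0.447, against 0.636 to 0.911 in the other 9. Replicates correlated across transcripts between 0.747 (KO UUO) and 0.933 (WT normal), and the first principal component, 27.4% of the variance, set these 3 libraries apart.

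**Figure D1:**
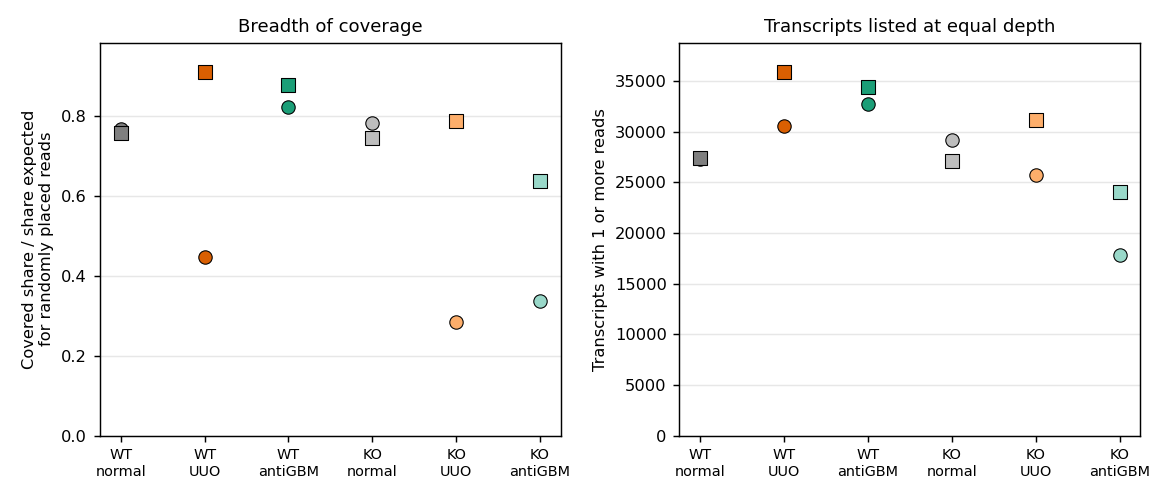
Breadth of coverage (left; covered length over the length that randomly placed reads would cover, no unit) and number of transcripts with 1 or more reads after thinning every library to 4595261 reads (right). Each point is 1 library, circles replicate 1 and squares replicate 2, by group; WT UUO 1, KO UUO 1 and KO anti-GBM 1 sit between 0.285 and 0.447 on the left, below the other 9.

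UUO in WT kidneys changed noncoding transcripts in both directions. The 2643-base transcript ncRNA_aligned_943, in a predicted conserved structure (EvoFold), rose from 10.2 ± 1.78 to 578 ± 39.5 CPM (SD, n = 2), a log2 fold change of 5.82 ± 0.60 (SE). Others that rose were ncRNA_aligned_967 (mouse long noncoding RNA entry, log2 7.32 ± 1.21), ncRNA_aligned_1008 (cDNA AK008079, 6.81 ± 1.06), ncRNA_aligned_7825 (AK080205, 6.77 ± 1.14) and ncRNA_aligned_2317 (5.88 ± 0.83). The last matches a selenocysteine insertion sequence, the hairpin that makes ribosomes read a stop codon as selenocysteine. Transcript ncRNA_aligned_4910 (AK020541) fell from 79.1 ± 23.3 to 0.349 ± 0.138 CPM, log2 -7.81 ± 0.81, and ncRNA_aligned_6640 (mouse long noncoding RNA entry) from 86.3 ± 2.5 to 0.741 ± 0.217 CPM, log2 -6.86 ± 0.80. Further falls were those of ncRNA_aligned_7977 (AK039394, -5.93 ± 0.89), ncRNA_aligned_3502 (AK042638, -5.20 ± 0.86) and ncRNA_aligned_2421 (AK014162, -5.17 ± 0.84).

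In all, 600 of 24816 tested transcripts passed in WT UUO against WT normal, 169 higher and 431 lower (edgeR quasi-likelihood test, adjusted p under 0.05). The matched transcripts gave 98 higher and 305 lower, the predicted ones 71 higher and 126 lower. The surplus of falls depends on the scaling. It was smaller with DESeq2 size factors, at 248 higher and 333 lower. With library size alone 886 were higher and 137 lower, since the median of all transcripts then shifted by 1.05 on the log2 scale. The count was 138 and 135 without WT normal 1 or 2, 173 without WT UUO 1, and 1186 and 1213 without KO UUO 1 or 2. Of the 10 transcripts named above, the calls of ncRNA_aligned_943, ncRNA_aligned_7825, ncRNA_aligned_2317, ncRNA_aligned_4910, ncRNA_aligned_6640 and ncRNA_aligned_2421 held in each of the 12 fits without 1 library. Without WT normal 1 the call of ncRNA_aligned_967 was lost, without WT normal 2 that of ncRNA_aligned_7977, without either that of ncRNA_aligned_1008, and without either WT UUO library that of ncRNA_aligned_3502; the highest adjusted p among these was 0.157. In the 9 libraries of higher breadth, where the UUO groups and KO anti-GBM hold 1 library each, 9 of the 10 passed and ncRNA_aligned_1008 did not (adjusted p = 0.123).

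Among transcripts that match known elements, the one matching a regulatory element in the 5′ untranslated region of Spi1, which encodes the myeloid transcription factor PU.1, rose in WT UUO from 3.44 ± 0.0341 to 47.8 ± 4.15 CPM (ncRNA_aligned_3717, log2 3.79 ± 0.90, adjusted p = 0.025). Without 1 library its call was kept in 8 of 12 fits, and it was lost in the 9 libraries of higher breadth (adjusted p = 0.208). The transcript of the mir-135a-1 precursor, ncRNA_aligned_6360, fell from 589 ± 14.7 to 74.9 ± 33 CPM (log2 -2.98 ± 0.45, adjusted p = 0.000765) and kept its call in 12 of 12. Of 12 tested transcripts matching selenocysteine insertion sequences, 1 rose and 6 fell, with a median log2 change of -2.40; ncRNA_aligned_6494 fell by 2.71 ± 0.40. As a class they moved down (camera adjusted p = 1.01e-07), a call lost with an estimated correlation (adjusted p = 0.257). The vimentin element, from the mRNA of an intermediate filament protein of mesenchymal cells, stood at 169 ± 40.5 CPM in WT normal and 491 ± 203 CPM in WT UUO (log2 1.54 ± 0.50, adjusted p = 0.115; 0.000335 in the 9 libraries of higher breadth and 0.0184 by DESeq2). These elements and classes were chosen after the transcript names were seen, since none of the gene lists fixed earlier had 5 members in the tables, and a match to an element is not a measurement of that gene's whole mRNA.

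Glomerulonephritis in WT kidneys left 2 transcripts higher and 3 lower, a split that rests on the scaling (7 and 5 with DESeq2 size factors, 74 and 4 with library size alone). In 20 simulations with unchanged groups up to 12 transcripts were called in this comparison. The count of 5 does not exceed this highest count. These simulations gave each transcript the same spread in all groups. The replicates compared here differed less, with a chi-square per degree of freedom of 21.48 in WT normal and 38.54 in WT anti-GBM, against 474.6 in KO anti-GBM. The simulations therefore cannot decide whether the 5 exceed chance. Transcript ncRNA_aligned_1008 rose from 0.539 ± 0.158 to 80.2 ± 66.4 CPM (log2 7.17 ± 1.07) and ncRNA_aligned_943 from 10.2 ± 1.78 to 119 ± 54.5 CPM (3.54 ± 0.54, adjusted p = 0.0276). Transcript ncRNA_aligned_6640 fell to 5.58 ± 0.123 CPM (log2 -3.95 ± 0.69), ncRNA_aligned_2560 (AK151264, 486 bases) from 34.7 ± 13.8 to 0.231 ± 0.0185 CPM (-7.12 ± 1.13), and the predicted transcript ncRNA_predict_6171 from 26.7 ± 4.83 to 0.449 ± 0.29 CPM (-5.82 ± 1.01); these 4 shared an adjusted p of 0.0399, with ncRNA_aligned_1008 among them. Its call was lost in the 9 libraries of higher breadth (adjusted p = 0.131) and without WT anti-GBM 1, WT normal 1, WT normal 2 or WT UUO 2. The architectural RNA of paraspeckles, Neat1 (ncRNA_aligned_3989), was at 121 ± 55.7 CPM in WT normal and 1050 ± 713 CPM in WT anti-GBM, a log2 change of 3.11 ± 0.78 that did not pass (adjusted p = 0.299; 0.227 in the 9 libraries of higher breadth) and that DESeq2 called (adjusted p = 0.00203). DESeq2 called 199 transcripts, and other fits far more: 1620 in the 9 libraries of higher breadth (706 higher and 914 lower), 2246 in a fit of only these groups, 2615 with voom quality weights and 540 with breadth as a covariate. Not every fit did so: limma on log2 of RPKM plus 0.1 called 0 (3601 at an unadjusted p under 0.05), and other settings listed below called few. In the simulated counts limma on RPKM plus 1 recovered 42% of changes of log2 size 4, against 94% by edgeR. The setting plus 0.1 was not simulated. A count of 0 by limma thus need not mean that nothing changed. With 12 libraries the unadjusted edgeR p fell under 0.05 for 1627, against 1241 by chance alone. No call was left without WT normal 1, WT normal 2 or WT anti-GBM 1, while the count was 15 and 18 without KO anti-GBM 1 or 2, 12 without WT UUO 1, and 58 and 63 without KO UUO 1 or 2.

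All 5 transcripts called in WT anti-GBM were also called in WT UUO, in the same direction: ncRNA_aligned_1008 and ncRNA_aligned_943 higher, and ncRNA_aligned_6640, ncRNA_aligned_2560 and ncRNA_predict_6171 lower. Both comparisons share the WT normal libraries. In 20 simulations with unchanged groups on shared controls, at most 16 transcripts were called in WT UUO and 12 in WT anti-GBM. A mean of 1.3 and at most 3 transcripts were higher in both, and a mean of 0.35 and at most 2 lower in both. Independent lists would share 0.0136 and 0.0521. Across transcripts, which are not independent replicates, the fold changes of both models correlated at 0.718, against 0.568 in the simulations. The overlap was 15 and 17 without KO anti-GBM 1 or 2, 11 without WT UUO 1, and 54 and 59 without KO UUO 1 or 2, and no transcript was shared without WT normal 1, WT normal 2 or WT anti-GBM 1. In the 9 libraries of higher breadth, with 1 WT UUO library and no simulation of their own, 426 were higher and 709 lower in both, and 1 went opposite ways.

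The 2 models also differed within WT. Transcript ncRNA_aligned_2048 (AK032794, 11264 bases) was at 378 ± 146 CPM in UUO and 14.1 ± 0.639 CPM in anti-GBM, a log2 difference of 4.75 ± 0.52 (adjusted p = 9.04e-05). The selenocysteine-element transcript ncRNA_aligned_2317 was higher in UUO by 4.30 ± 0.75, and ncRNA_aligned_6819, which matches a B2 short interspersed repeat, by 3.79 ± 0.69. Transcript ncRNA_aligned_4910 was lower in UUO by a log2 difference of -5.70 ± 0.75, and ncRNA_aligned_8234, with a gammaretrovirus packaging signal, of -3.03 ± 0.49. In total 15 transcripts were higher and 9 lower in UUO. Without 1 library the count was 8 and 8 (WT normal 1 or 2), 5 and 13 (WT anti-GBM 1 or 2), 10 (WT UUO 1), and 69 and 80 (KO UUO 1 or 2), and only the calls of ncRNA_aligned_2048 and ncRNA_aligned_4910 among those named here held in all 12 fits.

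In KO kidneys UUO raised 3 transcripts past the test. They were ncRNA_aligned_6916 (AK036034, 11781 bases), from 138 ± 0.309 to 1420 ± 133 CPM (log2 3.36 ± 0.44, adjusted p = 0.00194), ncRNA_aligned_1409 (AK083502), from 93.4 ± 54.5 to 683 ± 165 CPM (2.87 ± 0.48), and ncRNA_aligned_1946 (AK016173), from 1090 ± 88.4 to 6500 ± 2290 CPM (2.58 ± 0.44), the last pair at adjusted p = 0.0435. In WT the levels of ncRNA_aligned_6916 were 89.3 ± 14.3 CPM in normal and 1140 ± 548 CPM in UUO kidneys. At an unadjusted p under 0.05, 783 transcripts were lower in KO UUO, and 1483 differed in either direction against 1241 by chance alone. None of the 24816 passed as lower (0 by edgeR), while DESeq2 called 122 in both directions together. The count was 16 and 7 without KO anti-GBM 1 or 2, 7 and 7 without WT anti-GBM 1 or 2, 1 without KO normal 1, WT normal 1 or WT normal 2, 5 without WT UUO 1 or WT UUO 2, and 184 without KO UUO 2, whose partner is 1 of the 3 libraries of low breadth.

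In KO kidneys with glomerulonephritis, a transcript that matches the packaging signal of gammaretroviruses, ncRNA_aligned_8234, went from 78.7 ± 43.2 to 1490 ± 440 CPM (log2 4.24 ± 0.52, adjusted p = 0.000638). In WT it was at 369 ± 4.26 CPM in normal and 1140 ± 524 CPM in anti-GBM kidneys, so the genotypes lay further apart in normal kidneys than in anti-GBM. Another transcript with this signal, ncRNA_aligned_8305, was at 11.8 and 7.49 CPM in KO normal and at 76.8 and 11 CPM in KO anti-GBM, with no call (2.18 ± 0.96, adjusted p = 0.559). Transcript ncRNA_aligned_4113 (AK133569) rose from 430 ± 120 to 7370 ± 1810 CPM (4.10 ± 0.53). In WT it was at 2170 ± 62.8 CPM in normal and 5630 ± 3990 CPM in anti-GBM kidneys. Transcript ncRNA_aligned_6640 rose from 0 reads to 15.1 ± 8.21 CPM (at least 46.8-fold), ncRNA_aligned_4212 (AK085897) from 204 ± 47.8 to 2100 ± 1090 CPM (3.36 ± 0.53), and the predicted ncRNA_predict_8223 from 0 reads to 18.6 ± 8.8 CPM (at least 57.8-fold). One transcript, ncRNA_aligned_931 (M25175), fell from 401 ± 77.9 to 8.18 ± 7.93 CPM (-5.60 ± 0.82); its call was lost without KO anti-GBM 1, KO normal 1, KO UUO 1 or KO UUO 2 (highest adjusted p = 0.0907) and in the 9 libraries of higher breadth (adjusted p = 0.192).

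Among the higher calls in KO anti-GBM, ncRNA_aligned_10503 and ncRNA_aligned_8284 match the same cDNA (AK037011), so calls need not be separate genes. The count in KO anti-GBM was 12 higher and 1 lower, with 113 by DESeq2. It was 13 and 2 with DESeq2 size factors and 13 and 5 with library size alone. At an unadjusted edgeR p under 0.05 the split turned, with 661 higher and 1510 lower. No call was left without KO normal 1, so these calls rest on that control library; the count was 6 without KO normal 2 and 20 without KO anti-GBM 2 or KO UUO 1. The highest adjusted p of ncRNA_aligned_8234 in the 12 fits without 1 library was 0.0793.

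**Figure D2:**
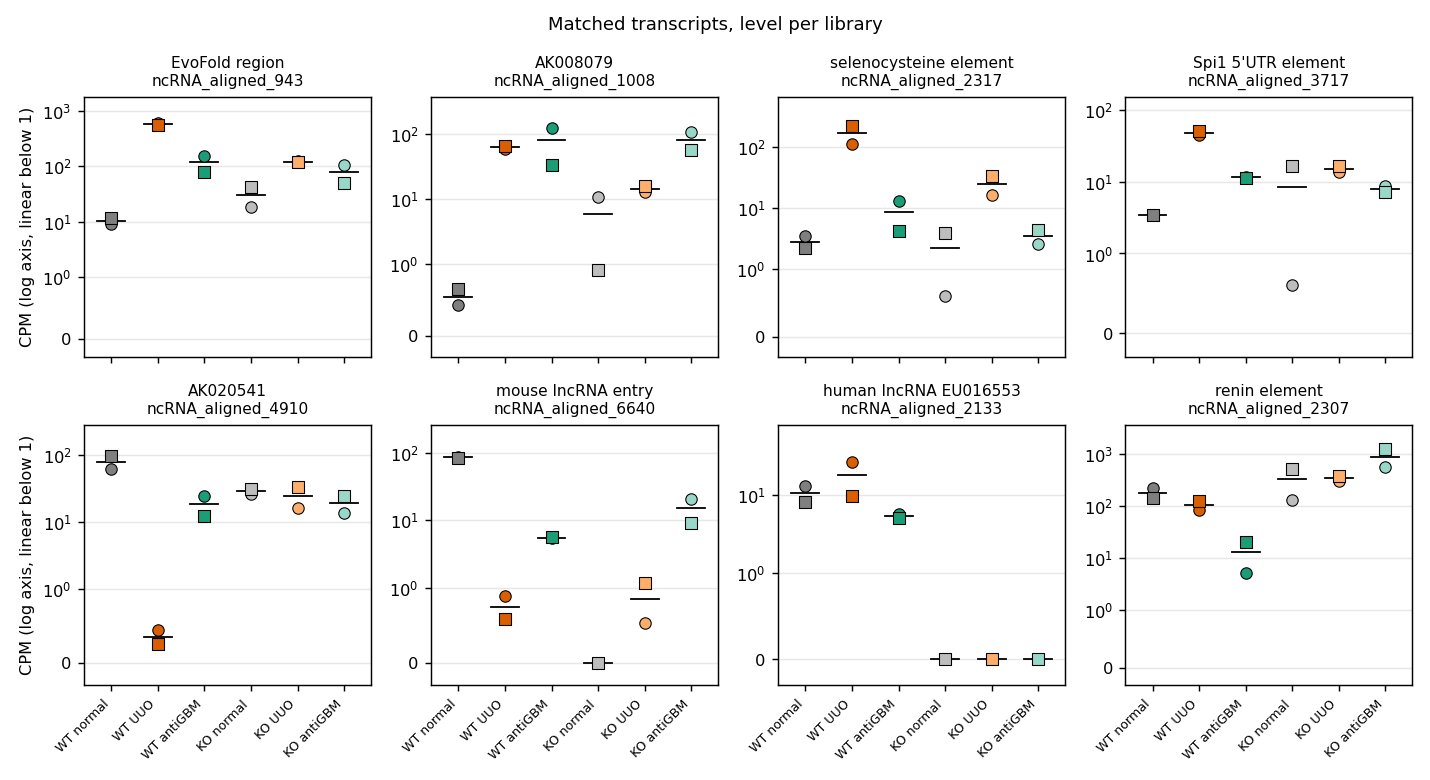
Level of 8 matched transcripts in each library (CPM scaled by TMM, log axis, linear below 1) by group; circles are replicate 1, squares replicate 2 and lines group means (n = 2). Transcript ncRNA_aligned_2133 sits at 0 in all 6 KO libraries, and ncRNA_aligned_943 reaches a mean of 578 CPM in WT UUO against 122 CPM in KO UUO.

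Normal KO kidneys differed from normal WT kidneys in 4 transcripts with 12 libraries, each lower in KO. Transcript ncRNA_aligned_6640 had 0 reads in both KO normal libraries and 86.3 ± 2.5 CPM in WT normal, at least 268-fold higher in WT (adjusted p = 2.56e-05). Transcript ncRNA_aligned_2560 had 0 reads in KO normal and was at least 108-fold higher in WT. Transcript ncRNA_aligned_2421 was at 0.872 ± 0.372 CPM in KO and 68.8 ± 21.9 CPM in WT (log2 -6.28 ± 0.92), and ncRNA_aligned_1946 at 1090 ± 88.4 and 7890 ± 1090 CPM (-2.86 ± 0.44). None was higher in KO in this fit (0 by edgeR), and DESeq2 called 43 in both directions. At an unadjusted p under 0.05, 268 were higher and 550 differed in either direction, fewer than the 1241 of chance alone. With DESeq2 size factors 0 were higher and 6 lower, and with library size alone 0 and 9. Other fits called both directions too: 55 higher and 129 lower in the 9 libraries of higher breadth, 119 in all in a fit of only these groups and 255 with voom quality weights. The call of ncRNA_aligned_6640 held in each of the 12 fits without 1 library; the count was 1 without KO normal 1 or WT normal 1, 2 without KO normal 2, 7 and 8 without KO anti-GBM 1 or 2, 9 without KO UUO 1 or KO UUO 2, and 7 and 10 without WT UUO 1 or 2.

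After UUO, KO and WT kidneys differed in 2 transcripts. Transcript ncRNA_aligned_4910, which UUO lowered in WT, was at 24.5 ± 12.2 CPM in KO UUO and 0.349 ± 0.138 CPM in WT UUO (log2 6.12 ± 0.76, adjusted p = 0.000928), and its call held in each of the 12 fits without 1 library. Transcript ncRNA_aligned_2133 was lower in KO, with 0 reads against 17.9 ± 11.9 CPM, at least 91.9-fold (adjusted p = 0.021); this call was lost without KO UUO 1, WT normal 1, WT normal 2 or WT UUO 1 (highest adjusted p = 0.08). DESeq2 called 111 transcripts, and 1510 had an unadjusted edgeR p under 0.05, against 1241 by chance alone. Without 1 library the count was 13 and 23 (KO UUO 1 or 2), 4 (KO anti-GBM 1 or 2) and 1 (WT normal 1, WT normal 2 or WT UUO 1).

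With glomerulonephritis, KO kidneys had higher levels of 4 transcripts than WT. The transcript that matches the stability element of renin mRNA, whose product starts the angiotensin cascade, was at 900 ± 478 CPM in KO and 12.9 ± 10.9 CPM in WT (ncRNA_aligned_2307, log2 6.13 ± 0.84, adjusted p = 0.0315). Its mean was 182 CPM in WT normal, 326 CPM in KO normal, 105 CPM in WT UUO and 346 CPM in KO UUO. Transcripts ncRNA_aligned_6523 (EvoFold region, 3.25 ± 0.49), ncRNA_aligned_2187 (3.17 ± 0.51) and ncRNA_aligned_3665 (2.70 ± 0.46), the last pair in conserved structures predicted by RNAz, were also higher. The predicted ncRNA_predict_3772 was lower in KO, at 2.55 ± 1.41 against 48.4 ± 16.1 CPM (-4.22 ± 0.74). The mir-135a-1 precursor transcript, at 594 ± 221 CPM in KO and 123 ± 14.6 CPM in WT, missed the threshold (2.27 ± 0.44, adjusted p = 0.0519; 0.000672 in the 9 libraries of higher breadth and 0.00351 by DESeq2).

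These were 5 calls by edgeR, against 531 by DESeq2. The call of the renin-element transcript was lost without KO anti-GBM 2, KO UUO 1 or WT anti-GBM 1 (highest adjusted p = 0.104) and in the 9 libraries of higher breadth (adjusted p = 0.113). No call was left without KO anti-GBM 2 or WT anti-GBM 1, and the count was 22 without KO anti-GBM 1, 3 without KO normal 1, KO normal 2, WT normal 1 or WT normal 2, 94 without KO UUO 1 or KO UUO 2, and 47 and 49 without WT UUO 1 or 2. With library size alone as scaling 209 transcripts were lower and 5 higher in KO, as the median of all transcripts shifted by -0.75 on the log2 scale.

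Predicted transcripts took 4.87 ± 0.0594% of reads in WT normal (SD, n = 2), 10.1 ± 1.14% in WT UUO and 7.88 ± 1.25% in WT anti-GBM, and in KO 5.12 ± 0.159%, 6.79 ± 1.26% and 4.03 ± 1.1%. The KO minus WT difference over the states was -2.32 percentage points, with exact two-sided p = 0.0556 over 216 arrangements within states. In KO against WT anti-GBM the 16781 tested predicted transcripts had a median log2 change of -1.17 (camera adjusted p = 1.59e-12; adjusted p = 0.142 with an estimated correlation; adjusted p = 0.0352 by fry). Small nucleolar and Cajal body RNAs, guides of RNA modification, had a median of -0.84 in KO UUO against KO normal (camera adjusted p = 3.66e-09; adjusted p = 0.564 with an estimated correlation), where KO UUO 1 is a library of low breadth. Of the camera calls over 18 classes, 12 in WT UUO, 16 in WT anti-GBM and 15 in KO against WT anti-GBM, none held with an estimated correlation. The KO anti-GBM group holds 1 of the libraries of low breadth and the WT anti-GBM group none.

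Averaged over the 3 states, 8 transcripts were higher and 2 lower in KO. The direction turned with library size alone, at 4 higher and 29 lower, and at an unadjusted p under 0.05 there were 742 higher and 1512 lower. The renin-element transcript was higher by a log2 difference of 2.89 ± 0.42 (adjusted p = 0.0351), a call lost without KO anti-GBM 2, KO UUO 1 or any of the WT normal and WT UUO libraries (highest adjusted p = 0.184) and in the 9 libraries of higher breadth (adjusted p = 0.212). Also higher were ncRNA_aligned_6523 (1.75 ± 0.26), ncRNA_aligned_6386 (AK085582, 1.51 ± 0.24) and ncRNA_aligned_2951 (mouse long noncoding RNA entry, 1.49 ± 0.23). Transcript ncRNA_aligned_2133 was absent from KO. Transcript ncRNA_aligned_6640 was called lower (adjusted p = 0.0125) because of normal kidneys alone, with 0 reads in KO against 86.3 CPM in WT. Its means in KO and WT were 0.852 and 0.741 CPM in UUO, and 15.1 and 5.58 CPM in anti-GBM, where KO was higher. Transcript ncRNA_aligned_8371 (AK088706), outside the rule for named transcripts, had means of 3.87 CPM in WT and 5.92 CPM in KO normal, 0 reads and 5.44 CPM in UUO, and 1.33 and 12.2 CPM in anti-GBM (adjusted p = 0.0455 for the average, a call kept in 4 of 12 fits). Xist, the RNA that coats the silenced X chromosome of females, was at 652 ± 888 CPM in KO normal and 543 ± 636 CPM in KO anti-GBM, against 11.3 ± 14.7 and 2.41 ± 1.25 CPM in the same WT states. By library it was at 24.2 and 1280 CPM in KO normal and at 93.3 and 993 CPM in KO anti-GBM. The labels name both genders for the UUO protocol alone, where Xist was at 0.84 CPM in WT and 0.715 CPM in KO. With the Xist level as a covariate 3 transcripts were called. The count was 1 without KO anti-GBM 2, WT normal 1 or WT normal 2, 4 without KO normal 1, 6 without WT UUO 2 and 189 without KO UUO 2.

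The response to UUO differed between genotypes for 15 transcripts. Transcript ncRNA_aligned_4910 fell in WT by 7.81 on the log2 scale and stood at 28.6 ± 3.92 and 24.5 ± 12.2 CPM in KO normal and KO UUO, an interaction of 7.59 ± 0.95 (adjusted p = 0.000461). Transcript ncRNA_aligned_2421 fell in WT and went from 0.872 ± 0.372 to 16.8 ± 3.64 CPM in KO (9.42 ± 1.20). Transcript ncRNA_aligned_943 had 30.7 ± 17.3 and 122 ± 2.47 CPM in KO, a smaller change than in WT (-3.82 ± 0.72, adjusted p = 0.0391). Over the 600 transcripts called in WT, 86.7% had the same sign in KO, the median absolute log2 change was 3.12 in WT and 1.13 in KO, and the slope of the KO on the WT response was 0.259. Transcripts picked for passing in WT have large WT values by selection. The slope was 0.192 in the 9 libraries of higher breadth and between 0.194 and 0.364 without 1 library.

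**Figure D3:**
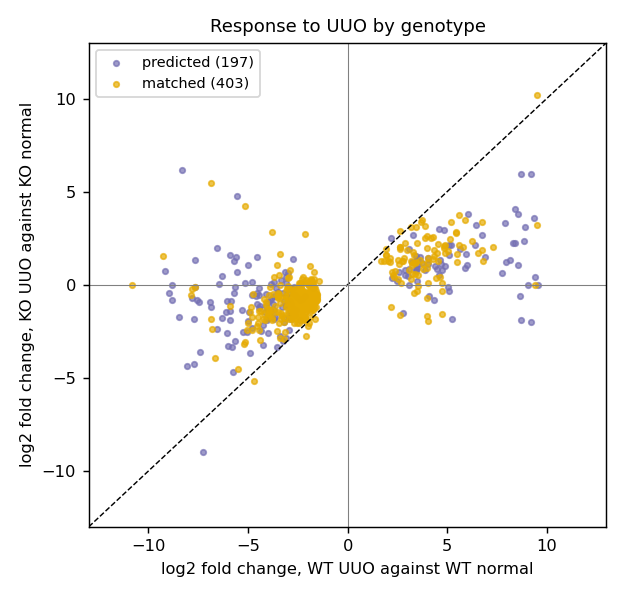
Response to UUO (log2 fold change against normal kidneys of the same genotype) in WT on the horizontal and KO on the vertical axis, for the 600 transcripts called in WT; 197 predicted and 403 matched transcripts are coloured apart and the dashed line marks equal responses. Most points lie nearer the horizontal axis than the dashed line, with a slope of 0.259.

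The interaction count for UUO was 6 without KO normal 1, KO normal 2 or WT UUO 2. It was 44 and 42 without KO UUO 1 or 2, and 4 and 3 without WT normal 1 or 2. For glomerulonephritis 4 transcripts passed: ncRNA_aligned_6640, which fell in WT and rose in KO (adjusted p = 4.37e-05), ncRNA_aligned_5045 (AK039219, 4.97 ± 0.85), the mir-135a-1 precursor transcript (3.52 ± 0.61) and ncRNA_predict_8223 (0 reads in KO normal). None was lower (0 by edgeR; 1789 lower at an unadjusted p under 0.05), and DESeq2 called 168 in both directions. This split rests on the scaling too, with 6 higher and 7 lower with DESeq2 size factors and 3 and 29 with library size alone. Without 1 library the count was 8 (KO anti-GBM 1), 1 (KO normal 1, WT normal 1 or WT anti-GBM 1), 2 (WT normal 2), 30 (KO UUO 1 or KO UUO 2), and 16 and 14 (WT UUO 1 or 2).

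In the 9 libraries of higher breadth the counts were larger in each of the 11 comparisons, between 118 (KO against WT UUO) and 2685 (WT UUO). With 12 libraries no transcript was both induced by UUO and anti-GBM in WT and lower in KO in both models. This count of 0 by edgeR compares with 25 at an unadjusted p under 0.05 in all 4 tests, and with 1 by DESeq2, ncRNA_aligned_2216 (AK163100). Its means were 2.38, 55.4 and 13.8 CPM in WT normal, UUO and anti-GBM, and 4.37, 10.6 and 2.47 CPM in KO. The mirror set, reduced in both models in WT and higher in KO, was also 0 by edgeR, with 94 at an unadjusted p under 0.05 and 4 by DESeq2. One of those 4, ncRNA_aligned_2951, had means of 10300, 691 and 2380 CPM in WT normal, UUO and anti-GBM, and 10300, 3360 and 10800 CPM in KO. In the 9 libraries of higher breadth, with 1 library each for WT UUO, KO UUO and KO anti-GBM, the induced set held 1 transcript and the mirror set 34, and without KO UUO 1 or KO UUO 2 the mirror set held 2.

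**Figure D4:**
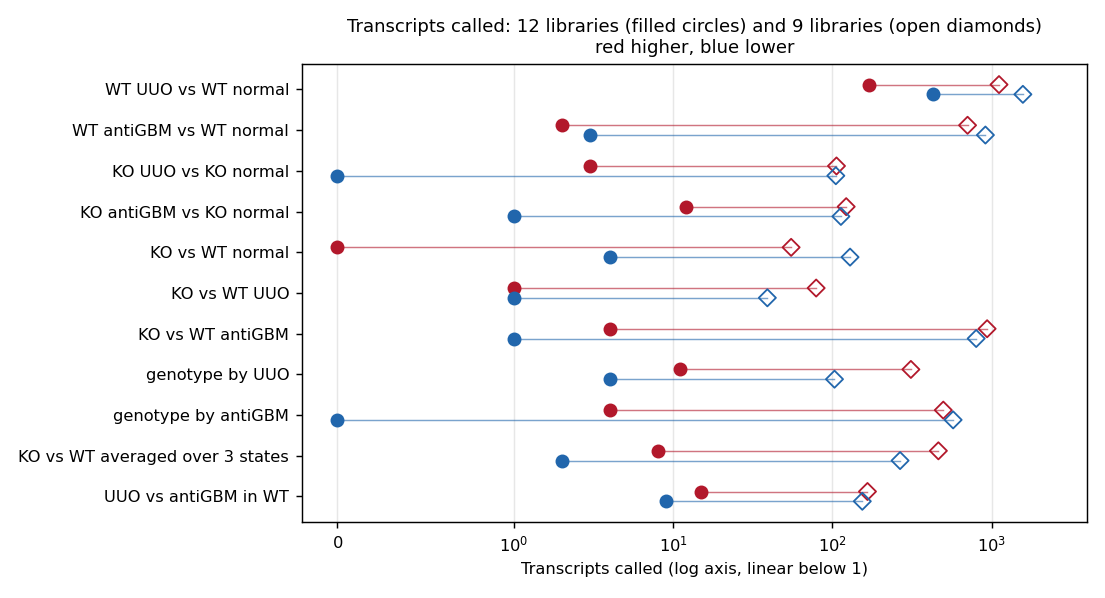
Transcripts called at adjusted p under 0.05 in each of 11 comparisons (log axis, linear below 1), higher in red and lower in blue. Filled circles are the fit of 12 libraries and open diamonds the fit of the 9 libraries of higher breadth; WT UUO against WT normal goes from 169 higher and 431 lower to 1113 and 1572.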

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

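Chosen only after results were seen were the fits of the 9 libraries of higher breadth and the fits with the Xist level as a covariate. So were the test of stacked reads and the test of library size for WT UUO 1 and KO UUO 1. The other tests here were set before their results, apart from a margin of 1 SD in the test of library size.

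A difference between WT and KO in the response to disease drew attention to 15 transcripts in UUO and 4 in anti-GBM, each by the test of the interaction. In UUO the response of ncRNA_aligned_6640, ncRNA_aligned_2421 and ncRNA_aligned_4910 was more positive in KO at a shared adjusted p of 0.000461, by log2 9.42 ± 1.20 and 7.59 ± 0.95 for the last pair. Transcript ncRNA_aligned_6640 had 0 reads in KO normal, which set at 3 counts over the group gives at least 8.27. The response was also more positive for ncRNA_aligned_999 (AK008073; 6.63 ± 1.14, adjusted p = 0.0199), ncRNA_aligned_4173 (4.84 ± 0.75, 0.00797), ncRNA_aligned_6576 (3.97 ± 0.72, 0.0461), ncRNA_aligned_4690 (AK017179; 3.69 ± 0.69, 0.0391) and ncRNA_aligned_1946 (3.59 ± 0.60, 0.0186). It was more negative in KO for ncRNA_aligned_4494 (AK156533; -6.34 ± 1.07, 0.0186), ncRNA_aligned_7971 (AK089828; -5.69 ± 1.04, 0.0335), ncRNA_aligned_2597 (AK134218; -5.11 ± 0.95, 0.0391) and ncRNA_aligned_943 (-3.82 ± 0.72, 0.0391). In anti-GBM it was more positive in KO for ncRNA_aligned_6640 (at least 9.50, adjusted p = 4.37e-05), ncRNA_aligned_5045 (4.97 ± 0.85, 0.0403) and the mir-135a-1 precursor transcript ncRNA_aligned_6360 (3.52 ± 0.61, 0.0403). Of the transcripts named here only ncRNA_aligned_6576 lost its call in the 9 libraries of higher breadth, where 3 groups hold 1 library each. More calls were lost in the 12 fits without 1 library. For UUO ncRNA_aligned_6640, ncRNA_aligned_2421 and ncRNA_aligned_4910 kept theirs in all 12. The call of ncRNA_aligned_4173 was kept in 8, of ncRNA_aligned_6576 in 5, of ncRNA_aligned_2597 in 4 and of each other one in 7. For anti-GBM ncRNA_aligned_6640 kept it in all 12, ncRNA_aligned_5045 in 6 and ncRNA_aligned_6360 in 5. Without 1 library the UUO count went from 3 (WT normal 2) and 4 (WT normal 1) through 6 (KO normal 1, KO normal 2 or WT UUO 2) to 42 and 44 (KO UUO 2 or 1). The anti-GBM count was 1 (KO normal 1, WT normal 1 or WT anti-GBM 1), 2 (WT normal 2), 8 (KO anti-GBM 1), 14 and 16 (WT UUO 2 or 1) and 30 (KO UUO 1 or KO UUO 2).

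The libraries WT UUO 1, KO UUO 1 and KO anti-GBM 1 stood apart from the other 9, and they come from 3 groups whose partners are among the 9. Of these 9, KO anti-GBM 2 had the lowest breadth ratio (0.636) and WT UUO 2 the lowest median correlation with the others (0.805). Library size is argued against for WT UUO 1 and KO UUO 1. Their median correlations with the others were 0.722 and 0.754 after thinning to equal totals, against 0.813 or more in the 9 (SD 0.0248). For KO anti-GBM 1 thinning narrowed the gap from 0.789 against 0.805 to 0.807 against 0.813. The gap was kept in 20 of 20 thinnings, the outcome predicted if library size was not the cause. It is small beside that SD, a margin the prediction did not name, so library size stays open for this library. A bias by transcript length shared by the 3 is argued against, since the rank correlations of length with the ratio to the partner were -0.009 (0.00933 in size) for KO anti-GBM 1 and -0.049 for WT UUO 1, within -0.057 to 0.111 of the other pairs; that of KO UUO 1, -0.117, lay outside and stays open. Stacked reads from fewer distinct RNA fragments stay open: 3 of 3 listed fewer transcripts than the partner after thinning, too few pairs to decide, and since the 3 were picked by low breadth their ratio decides nothing. No biological explanation was tested, and degraded RNA or a separate library batch stays open.

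The response to UUO was smaller in KO than in WT over the transcripts called in WT. The slope of the KO on the WT response was 0.192 in the 9 libraries of higher breadth, 0.259 in all 12 and at most 0.364 (without KO UUO 2). Leaving out the libraries of low breadth thus did not raise it. Transcripts picked for large WT values lower the slope in each of these fits, so it cannot decide whether these libraries are a cause. Selection of extreme WT values stays open: among the transcripts called in KO in 9 libraries the slope of WT on KO was 0.465, above 0.192 yet below 1, so selection alone may lower both slopes. The loss of Smad3, which the design names, stays open beside it.

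The genotype difference averaged over the 3 states was called for 10 transcripts. A mix of sexes stays open. With the Xist level as a covariate the median absolute log2 difference of the 10 went from 1.70 to 1.87. Without the covariate it was also 1.70 with groups at 0 reads set to the floor. This was the outcome predicted if sex was not the cause. Only 1 of the 10 stayed called, and the median standard error rose from 0.28 to 0.45. The test cannot decide, as a high Xist level was seen in KO alone. Xist was at 1280 CPM in KO normal 2 and 993 CPM in KO anti-GBM 2, and at most 21.7 CPM in WT (WT normal 2). The libraries of low breadth stay open as a cause. All but the renin-element transcript kept their call in the 9 libraries of higher breadth, and all kept their direction. This cannot decide, since the 10 were picked in a fit that holds the same 9 libraries, and 3 groups then hold 1 library each. Chance cannot be excluded: of 100 splits of the genotype labels within states, drawn from 108, 21 gave 10 or more calls, the real one included, and the highest other gave 621. That highest count points to a structure of the samples, as the 17 splits with the 3 libraries of low breadth on 1 side gave 5 to 621 calls and the others at most 57; without 1 library the real count was between 1 (KO anti-GBM 2, WT normal 1 or WT normal 2) and 189 (KO UUO 2), with 4 (KO normal 1) and 6 (WT UUO 2) between.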

How the results depend on the processing

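The fits of 9 libraries, voom with quality weights, both covariates and the fits with the filter applied again were chosen after seeing the data. Counts are listed in the order WT UUO, WT anti-GBM, KO UUO and KO anti-GBM against normal, KO against WT in normal, UUO and anti-GBM kidneys, the interactions for UUO and anti-GBM, the averaged genotype, UUO against anti-GBM in WT, and the overlap of both models in WT. With 12 libraries and edgeR they were 600, 5, 3, 13, 4, 2, 5, 15, 4, 10, 24 and 5. A required absolute log2 fold change of 1 left each of these counts as it was. DESeq2 size factors gave 581, 12, 2, 15, 6, 9, 30, 18, 13, 12, 42 and 12. Library size alone gave 1023, 78, 63, 18, 9, 24, 2.1e+02 (5 higher and 209 lower), 28, 32, 33, 59 and 71; it shifted the median log2 change of all transcripts by 1.05 in WT UUO and by -0.75 in KO against WT anti-GBM. The DESeq2 Wald test gave 1408, 199, 122, 113, 43, 111, 531, 142, 168, 149, 2.1e+02 (122 higher and 92 lower) and 162. Without a filter on low counts the list was 1046, 123, 1.1e+02 (39 higher and 67 lower), 84, 56, 91, 183, 133, 78, 77, 163 and 107, with the prior degrees of freedom infinite against 17.4. The stricter filter gave 715, 23, 18, 18, 9, 22, 52, 39, 18, 26, 53 and 21. Fits of only the groups compared cannot give the averaged genotype; the others were 674, 2246, 0, 0, 119, 0, 0, 4, 31, 2 and 84. On log2 of RPKM plus 1, limma gave 1752, 1, 0, 0, 2, 6, 0, 0, 0, 0, 17 and 1, and on RPKM plus 0.1 it gave 245, 0, 1, 6, 1, 0, 18, 0, 0, 0, 0 and 0. Where a single comparison stood at 0, between 563 and 2629 transcripts (only the groups compared) and between 1484 and 6524 (limma) had an unadjusted p under 0.05, and DESeq2 gave the counts listed above. The 9 libraries of higher breadth, which leave 1 library each in WT UUO, KO UUO and KO anti-GBM, gave 2685, 1620, 211, 235, 184, 118, 1737, 414, 1070, 729, 320 and 1135, and with the filter applied again 3041, 1988, 323, 370, 279, 243, 2064, 585, 1423, 1011, 464 and 1354. Voom with quality weights gave 2316, 2615, 7, 18, 255, 0 (866 at an unadjusted p under 0.05), 71, 17, 249, 6, 168 and 1015. Breadth as a covariate gave 2039, 540, 62, 34, 52, 282, 612, 272, 210, 531, 163 and 490, and the Xist level as a covariate 410, 20, 2, 18, 3, 4, 1, 29, 17, 3, 33 and 18. The set induced in both models in WT and lower in KO, 0 by edgeR with 25 at an unadjusted p under 0.05, held 1 transcript with DESeq2, with 9 libraries and with breadth as a covariate, and 4 with 9 libraries and the filter applied again. The mirror set, 0 by edgeR with 94 at an unadjusted p under 0.05, held 1 with DESeq2 size factors, 4 with the DESeq2 Wald test, 8 without a filter, 3 with the stricter filter, 34 with 9 libraries, 68 with the filter applied again and 85 with breadth as a covariate. Without 1 library, on the same transcripts, the counts ran from 135 (WT normal 2) to 1213 (KO UUO 2), 0 (WT anti-GBM 1) to 63 (KO UUO 2), 1 (KO normal 1) to 184 (KO UUO 2), 0 (KO normal 1) to 20 (KO anti-GBM 2), 1 (KO normal 1) to 10 (WT UUO 2), 1 (WT normal 1) to 23 (KO UUO 2), 0 (KO anti-GBM 2) to 94 (KO UUO 1), 3 (WT normal 2) to 44 (KO UUO 1), 1 (KO normal 1) to 30 (KO UUO 1), 1 (KO anti-GBM 2) to 189 (KO UUO 2), 5 (WT anti-GBM 1) to 80 (KO UUO 2) and 0 (WT anti-GBM 1) to 59 (KO UUO 2); the induced set held 0 in each and the mirror set 0 to 2. With the filter applied again they were 414 to 1953, 11 to 307, 41 to 1341, 28 to 535, 14 to 90, 57 to 370, 43 to 568, 41 to 329, 18 to 295, 22 to 812, 57 to 448 and 9 to 262, the induced set 0 to 2 and the mirror set 0 to 17; 32560 to 35973 transcripts entered, and the prior degrees of freedom of the spread became infinite. The lone library of a group is assumed to vary like the others. Outside the settings whose construction is named here, the cause was not tested.

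Of the 75 results named by the rule none reversed in the alternatives run for them. Library size alone, the stricter filter and the fits with the filter applied again were not among these alternatives. The rule takes the largest fold changes among calls, so a reversal in refits of the same libraries was unlikely from the start. In the 900 fits without 1 library 673 kept their call and 227 lost it, most often without WT normal 2 (37), WT normal 1 (36) and KO normal 1 (29), and 17 of the 75 kept it in all 12. All 75 kept their calls with the DESeq2 Wald test and without a filter, 74 with breadth as a covariate, 72 with DESeq2 size factors, 68 in the 9 libraries of higher breadth, 62 with voom, 56 with the Xist level as a covariate, 30 of 69 in only the groups compared, and 22 and 18 with limma on RPKM plus 0.1 and plus 1. In the simulated counts limma on RPKM plus 1 missed more true changes than edgeR. The alternatives for the fixed gene lists gave no value, as no list had 5 members in the tables. With 4595261 to 7342937 reads per library, 24816 of 42452 transcripts passed the filter and were tested.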

Other observations

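The transcripts and classes of this part, and the fits of 9 libraries, were chosen after seeing the data. Several transcripts that match elements of mRNAs or microRNA genes did not pass the edgeR test in 12 libraries and are given as values. The one with the ribosome entry site of c-myc, ncRNA_aligned_683, was at 14.4 ± 2.9 CPM in WT normal (SD, n = 2), 75.4 ± 10 in WT UUO and 92 ± 98 in WT anti-GBM, and at 19.1 ± 9.1, 26.4 ± 13.8 and 42 ± 12.4 CPM in KO. Its log2 change in WT UUO was 2.39 ± 0.70 (adjusted p = 0.0791, and between 0.0247 and 0.513 without 1 library, with a call in 4 of 12 fits; 0.346 in the 9 libraries of higher breadth and 0.00607 by DESeq2). The one with the CAESAR element of connective tissue growth factor, ncRNA_aligned_6524, stood at 203 ± 136 CPM in KO normal and 656 ± 239 CPM in KO anti-GBM (1.69 ± 0.48, adjusted p = 0.436, and between 0.172 and 0.95 without 1 library; 0.23 in the 9 libraries and 0.0821 by DESeq2), and at 156 ± 34.9 and 241 ± 91.3 CPM in the same WT states. The transcript of the mir-200b precursor, ncRNA_aligned_7267, was at 15.6 ± 1.31 CPM in KO anti-GBM and 48.9 ± 4.46 CPM in WT anti-GBM (-1.65 ± 0.54, adjusted p = 0.244, and between 0.125 and 0.709 without 1 library; 0.0501 in the 9 libraries and 0.0528 by DESeq2). Reads on the transcript with the destabilising element of G-CSF, ncRNA_aligned_11387, were seen in the WT UUO libraries alone, at 1.79 and 7.89 CPM (adjusted p = 0.15 against WT normal, and between 0.0606 and 0.621 without 1 library; 0.00248 in the 9 libraries). The host transcript of Mir155, ncRNA_aligned_8024, was at 0.644 ± 0.298 CPM in WT normal and 4.97 ± 5.56 CPM in WT UUO (log2 change 2.92, adjusted p = 0.348, and between 0.23 and 0.872 without 1 library; 0.00575 in the 9 libraries and 0.137 by DESeq2).

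Among transcripts picked outside the rule, the predicted ncRNA_predict_17856 had means of 0.214, 0.63 and 1.8 CPM in WT normal, UUO and anti-GBM. In KO it had 1.82 and 0.167 CPM in normal and UUO and 0 reads in anti-GBM. The predicted transcript ncRNA_predict_5318 was looked up by its number, which was known from published work on Smad3 in kidney. Whether that work used these same libraries is not recorded, so the values below are not independent support for it. That the number names the same sequence there and here is not recorded either. In WT its mean was 1.40 CPM in normal, 6.47 CPM in UUO and 10.3 CPM in anti-GBM kidneys, and in KO 3.49 and 0.418 CPM in normal and UUO kidneys and 0 reads in anti-GBM, at least 30.9-fold lower than in WT anti-GBM. The test of KO against WT anti-GBM gave an adjusted p of 0.0623 with 12 libraries, 0.000553 in the 9 libraries of higher breadth and 0.0117 to 0.404 without 1 library, with a call in 4 of 12 fits. Its interaction for anti-GBM had an adjusted p of 0.159 with 12 libraries and 0.000493 with 9.

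The 9 libraries of higher breadth leave 1 library each in WT UUO, KO UUO and KO anti-GBM, so calls there rest on the spread of the other groups. The mirror set, reduced in both WT models and higher in KO in both, held 34 transcripts there, 24 of them among the 94 found with 12 libraries at an unadjusted p under 0.05. One of the 34, ncRNA_aligned_6386, had means of 4900, 443 and 1130 CPM in WT normal, UUO and anti-GBM, and 7620, 1870 and 3980 CPM in KO. The anti-GBM responses of WT and KO correlated at -0.069 with 12 libraries and -0.116 with 9. Transcripts that match the Air RNA, 17 in number, had a median log2 difference of -1.80 in KO against WT anti-GBM (camera adjusted p = 0.00441; 0.147 with an estimated correlation; 0.0139 by fry).

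In all, 16 transcripts, ncRNA_aligned_2133 among them, were listed in each of the 6 WT libraries and in no KO library, against 53 in the highest of the other arrangements of the genotypes. Whether ncRNA_aligned_2133 lies near the deleted gene is not known here, as the tables give no coordinates.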
